A study of Homo sapiens with 6 samples.

How the data were processed

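Total RNA of U251 glioma cells was hybridised to Affymetrix HG-U133 Plus 2 arrays, 3 from cultures on aligned and 3 from cultures on random poly-caprolactone nanofibers. Per the labels, cells grew for 24 h on coated 60 mm dishes in medium with 10% serum, RNA was purified, and biotinylated cRNA was made from 10 µg of it. Groups and replicate numbers were taken from the sample titles. The deposited table holds log2 values, 1 per probe set and array, which the authors made with RMA, per the submitters' processing notes. RMA corrects the background, brings the arrays to a common distribution and summarises the probes of each set. Its version and settings are not given in the sources used here. Sorted values of the 6 arrays deviated from their mean at each rank by at most 0.07 log2 units, with 0 missing values. Array medians lay between 5.63 and 5.66. Scanner files and detection calls were not used here, so a dim probe set could be recognised only by its rank within the array.

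The 62 control probe sets were set aside, leaving 54613. A probe set was kept when at least 3 of the 6 arrays lay above their own median over these, which left 27621. According to the platform annotation 41091 probe sets had 1 gene symbol, 1801 had several and 11721 had none. Of those with 1 gene, 41037 matched the human RefSeq gene table by gene identifier, and 0 symbols needed an update. Probe sets with several symbols were not used to name genes. Each gene was represented by the kept probe set with the highest mean over all arrays, which gave 12381 genes, 6162 of them with several kept probe sets. No genome build belongs to the values, so coordinates are not given.

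The comparison was aligned minus random. It was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with default prior and no covariate, on genes and on probe sets. Tests were two-sided with 4 residual degrees of freedom per gene before shrinkage, and p-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.10. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 37 lists with at least 5 measured genes out of 40, and beside it with an estimated correlation and with fry. Camera compares a list with the other genes, whereas fry tests whether the genes of a list move on balance in 1 direction. The control probe sets were compared by an exact permutation test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

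The lists, the tests, most alternatives and the rule for named genes were set before the data were examined. The rule took the 12 genes with the largest log2 change in each direction among those past the adjusted threshold, filled up to 12 with the smallest unadjusted p where too few passed. It also took up to 4 members of each list with the smallest unadjusted p, and 9 genes of migration, matrix, adhesion and glial identity. Lists without a called member could be summarised. For 1 gene taken by the first part of the rule and 1 taken by the second, no description is reported here. None of the 40 lists was chosen on these samples, but the stress list was divided into 8 and 17 genes after its values were seen.

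Replicate numbers 1 to 3 occur in both groups, and the labels give the number with no statement of what it shares. Deviations from the group means correlated across genes by 0.369, 0.322 and 0.109 between the arrays numbered 1, 2 and 3, so by a limit of 0.1 the numbers were taken to pair the arrays. The third value lay just above that limit, and with no filter on dim probe sets it was 0.0777. Aligned 2 and random 3, of different numbers, correlated by 0.188, while the other unequal numbers gave negative values. The limit thus does not single out equal numbers as pairs, and the pairing rests on the values and not on a label. The fit with the number as a block has 2 residual degrees of freedom and was run as an alternative. Gene counts, standard errors and list tests are those of the fit without the block unless it is named.

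Other alternatives were no filter, a filter at the 75th percentile, centring each array on its median, repeated quantile normalization, a trended robust prior, array weights, an ordinary two-sample test without shrinkage, an unadjusted p under 0.05 with a 1.5-fold change, the mean of all probe sets of a gene, omission of probe sets that share sequence with other transcripts by their suffix, and each array left out in turn. The estimate of array weights over genes stopped with a convergence warning, so the gene counts from that setting rest on weights that had not settled. The same settings were later applied to the counts of genes at an unadjusted p under 0.05 and of list members past the threshold over their list alone.

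The code was tested on simulated data with the spread of the 12381 genes and 3 arrays per group. Of 100 genes shifted by a log2 of 1, 96% were recovered, and of 100 shifted by 2, 99% were recovered. Of 205 calls, 10 were false. The shifted genes were picked at random, and no simulated array lay apart, so this recovery applies to genes of typical spread. In the data ABTB3 and CXCL3 differed by 1.38 ± 0.28 and 1.14 ± 0.22 (SE) and were not called, against a median standard error of 0.10. The recovery thus does not show how many real differences of that size were missed. A simulated list of 25 genes shifted by 0.4 had an adjusted p of 1.16e-40 with the preset and 0.00626 with an estimated correlation in camera, and 0 of 37 lists without a shift were called. The simulated genes were drawn independently of each other. In the data the estimated correlation ran from -0.13 for oligodendrocyte markers to 0.76 for cholesterol genes. The simulation therefore cannot show how often the preset test calls lists of correlated genes without a shift.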

Results

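Gene expression was measured in U251, an established human glioma cell line, grown on electrospun fibers of the polyester poly-caprolactone. In 3 cultures the nanofibers lay aligned with each other, and in 3 cultures they lay in random directions. RNA was collected after 24 h and read on Affymetrix arrays with 54675 probe sets, 1 array per culture. The cultures of each substrate are described as independent, so the spread between arrays includes the spread between cultures. After removal of dim probe sets, 12381 genes were compared. The question was which genes follow the topography of the substrate in migrating glioma cells.

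The array of aligned replicate 3 lay far from the other 5. The first principal component held 62.0% of the variance over the genes tested, with aligned 3 at 31.6 and the other arrays between -11.7 and 6.33. The root mean square distance to the mean of the random arrays was 0.38 log2 units for aligned 3, 0.19 for aligned 2 and 0.17 for aligned 1. Aligned 1 and random 1 were the most alike of all pairs of arrays, with a Pearson correlation across genes of 0.997. Signs of RNA quality were compared by an exact two-sided permutation test, which with 3 arrays against 3 cannot give a p below 0.1. The 3' minus 5' signal of GAPDH was 0.14 ± 0.04 log2 units on aligned and 0.10 ± 0.02 on random fibers (SD, n = 3, exact permutation p = 0.3). For beta-actin it was 0.15 ± 0.06 on aligned and 0.20 ± 0.03 on random fibers (SD, n = 3, exact permutation p = 0.3). The probe sets for 18S ribosomal RNA read 9.12 ± 0.63 on aligned and 8.77 ± 0.37 on random fibers (SD, n = 3, exact permutation p = 0.5), and aligned 3 alone read 9.78.

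**Figure D1:**
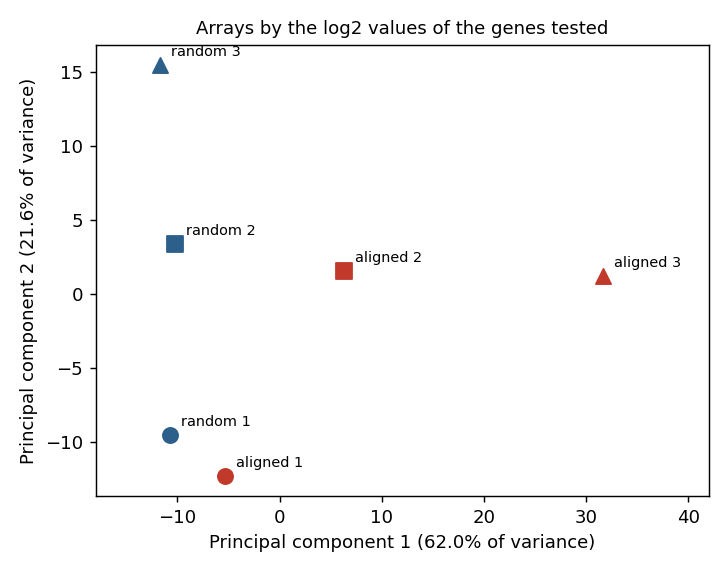
Positions of the 6 arrays on the first 2 principal components of the log2 values of the genes tested, with the share of variance of each component on its axis. Red marks stand for aligned and blue marks for random fibers, and circle, square and triangle stand for replicates 1, 2 and 3. Aligned 3 lies at 31.6 on the first component and the other 5 arrays between -11.7 and 6.33.

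Some gene lists shifted on aligned fibers in a test with a preset correlation between genes, while no single gene passed the test over all genes. Immediate early genes, the growth factor-induced regulators that respond first to a stimulus, rose with a median log2 difference of 0.36 (adjusted p = 0.587 with an estimated correlation). Inflammatory cytokines with NF-kB targets rose with a median of 0.17 (adjusted p = 0.587 with an estimated correlation), and the list of unfolded protein and amino acid stress genes with a median of 0.58 (adjusted p = 0.703 with an estimated correlation). Within that list, divided after its values were seen, 8 chaperone and degradation genes of the endoplasmic reticulum had a mean of -0.24 and the other 17 genes a mean of 0.72. Genes of cell cycle and mitosis fell by a median of 0.29, genes of neural stem cells fell by 0.44 and hypoxia targets fell by 0.24 (adjusted p = 0.752, 0.587 and 0.341 with an estimated correlation). These 6 lists were among 10 of 37 that passed limma's camera test with a preset correlation between genes of 0.01, and with an estimated correlation 0 of 37 passed, with 2 at an unadjusted p under 0.05. Of the 10 splits of the 6 arrays into 3 and 3, 5 gave as many lists in the preset test, the real split included. The highest other split gave 14.

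Among single genes, 0 of 12381 reached an adjusted p under 0.05 in limma with Benjamini-Hochberg adjustment, and the lowest adjusted p was 0.463. At an unadjusted p under 0.05 there were 1303 genes, or 10.5% of those tested, with 584 higher and 719 lower on aligned fibers, where chance alone gives 619. Of these, 220 also differed by at least 1.5-fold, 93 higher and 127 lower. An ordinary two-sample test without shrinkage called 0 genes at the adjusted threshold and 835 at the unadjusted one. On the level of probe sets, limma called 0 of 27621, with 2676 at an unadjusted p under 0.05. The 3 aligned arrays lay above all 3 random arrays in 1078 genes (8.71%) and below them in 1155 (9.33%), where chance gives 10% for both directions together. Weights per array raised the count to 2101 genes, a fit in which aligned 2 carried a weight of 15.2 and aligned 3 a weight of 0.245, and in which the estimate of the weights over genes stopped before it converged. The count of 1303 became 2491 without aligned 1, 815 without aligned 3, 739 without random 2 and 624 without random 3. Adjusted over each gene list alone, 26 list members passed, against 105 without aligned 1, 8 without aligned 2, 46 without random 1, 12 without random 2 and 5 without random 3.

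The 12 genes with the smallest unadjusted p among those higher on aligned fibers did not pass the test over all genes, each with an adjusted p of 0.463 in limma. S1PR1, a receptor for the lipid sphingosine 1-phosphate, read 6.64 ± 0.33 on aligned and 5.80 ± 0.04 on random fibers (SD, n = 3 each), a log2 difference of 0.84 ± 0.15 (SE), or 1.79-fold. The chemokine CXCL3 read 7.08 ± 0.44 against 5.94 ± 0.26, or 2.20-fold, and ABTB3 read 7.07 ± 0.45 against 5.68 ± 0.45, or 2.61-fold. The growth factors VEGFC and FGF5 differed by 0.49 ± 0.10 and 0.42 ± 0.08 (SE). The small GTPase GEM differed by 0.57 ± 0.11. The transcription factor ETS2 differed by 0.57 ± 0.11 and the chromatin protein HMGA1 by 0.49 ± 0.09. TMCC3, the anthrax toxin receptor ANTXR2 and the potassium channel gene KCNQ5 differed by 0.81 ± 0.15, 0.56 ± 0.11 and 0.45 ± 0.09.

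The 12 genes with the smallest unadjusted p among those lower on aligned fibers also had an adjusted p of 0.463 each in limma. ID2 and ID3, inhibitors of helix-loop-helix transcription factors and common targets of bone morphogenetic protein signalling, had log2 differences of -1.12 ± 0.20 and -0.67 ± 0.12 (SE). ID2 read 8.08 ± 0.16 on aligned and 9.20 ± 0.41 on random fibers (SD, n = 3 each), which is 2.17-fold higher on random fibers. The endothelin receptor gene EDNRB read 7.24 ± 0.27 against 8.12 ± 0.14, and its 3 probe sets differed by -1.26 to -0.88. ELMOD1 had the smallest p of all genes, 0.000139 before adjustment in limma, with 6.61 ± 0.16 on aligned and 7.30 ± 0.04 on random fibers. The glutamine transporter SLC38A3 differed by -0.78 ± 0.14, PDZRN3 by -0.73 ± 0.14, the fatty acid transport protein gene SLC27A3 by -0.60 ± 0.11, OBSL1 by -0.51 ± 0.09 and PLEKHA7, a protein of adherens junctions, by -0.43 ± 0.07. MIR210HG, the host transcript of a hypoxia-induced microRNA, differed by -0.59 ± 0.11, the mitochondrial adenylate kinase AK4 by -0.52 ± 0.11 and the pseudogene CASTOR3P by -0.43 ± 0.09. In all 24 genes the aligned and random values did not overlap, so the 3 differences between arrays of the same number had the same sign. The genes were picked for their small p, so this separation is no further evidence of a difference.

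**Figure D2:**
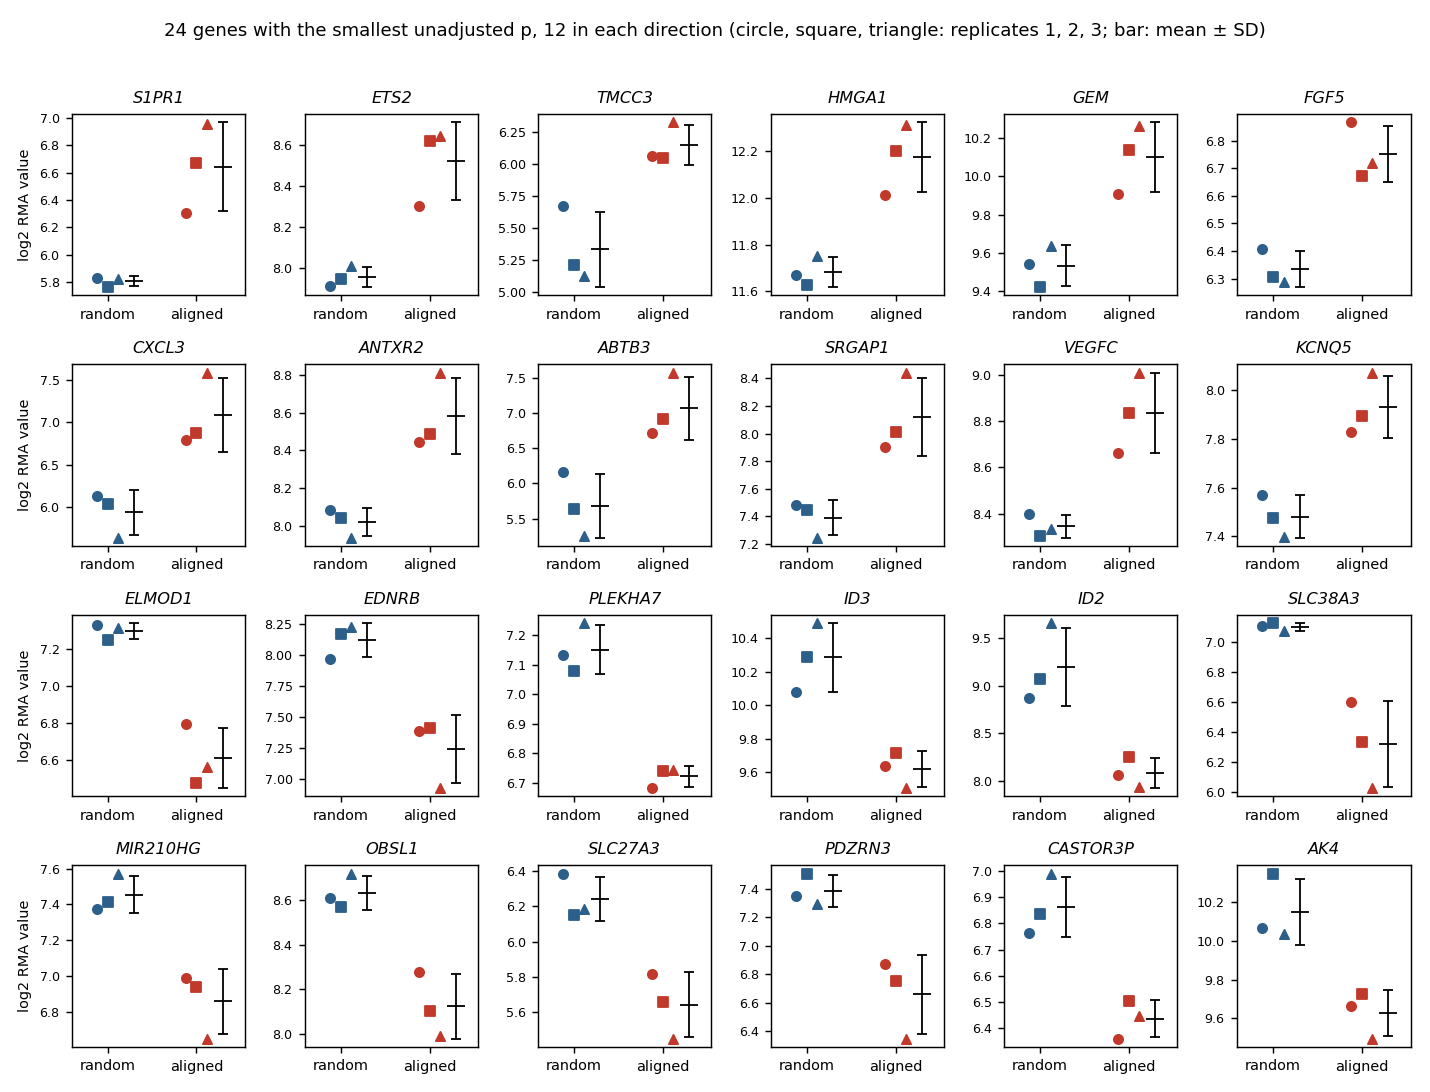
Deposited log2 values of the 24 genes with the smallest unadjusted p, 12 in each direction, on random (blue) and aligned (red) fibers, with each array as a point, its replicate number given by circle, square or triangle, and bars for the mean ± SD of 3 arrays. The vertical axes are log2 and do not start at 0. In each panel the 3 aligned points lie on 1 side of the 3 random points, and no gene passed the adjusted threshold.

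Immediate early genes rose on aligned fibers in the preset test (camera adjusted p = 1.39e-08; adjusted p = 0.587 with an estimated correlation). Of 23 measured members, 22 had a positive difference, 5 passed when adjusted over the list alone and 0 passed over all genes. The count of 5 became 8 without random 1, 2 without random 2, 1 without random 3 and 0 without aligned 2. The 5 genes were KLF2 at 1.44 ± 0.39 (SE), DUSP5 at 0.92 ± 0.23, DUSP4 at 0.63 ± 0.15, KLF6 at 0.57 ± 0.15 and SGK1 at 0.45 ± 0.11, of which KLF2 was named after its values were seen and was at 0.94 without aligned 3. KLF2 and KLF6 are transcription factors, DUSP4 and DUSP5 are phosphatases of MAP kinases, and SGK1 is a kinase induced by serum and glucocorticoids. The mean difference of the list was 0.19 between the arrays numbered 1, 0.27 between those numbered 2 and 0.79 between those numbered 3, where the distant array aligned 3 enters.

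Inflammatory cytokines and NF-kB targets rose in the same test (camera adjusted p = 0.000383; adjusted p = 0.587 with an estimated correlation). Of 14 measured genes 12 had a positive difference, and 4 passed when adjusted over the list alone against 0 over all genes. The count of 4 was 0 without random 3. The neutrophil-attracting chemokines CXCL8, CXCL3 and CXCL2 differed by 1.82 ± 0.48, 1.14 ± 0.22 and 0.92 ± 0.21 (SE), and TNFAIP3, a feedback inhibitor of NF-kB, by 0.48 ± 0.10. With the replicate number as a block, 7 members of this list passed when adjusted over the list alone. The list's median was 0.28 without random 1. The list mean differed by 0.20, 0.24 and 0.65 between the arrays numbered 1, 2 and 3.

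The unfolded protein and amino acid stress list rose as well (camera adjusted p = 0.000383; adjusted p = 0.703 with an estimated correlation). Of its 25 measured genes 18 had a positive difference, and 0 passed either over the list alone, where the lowest adjusted p in limma was 0.0556, or over all genes. Over the list alone 20 genes passed without aligned 1, 12 without random 1 and 21 with array weights. ASNS, which makes asparagine, differed by 1.11 ± 0.33 (SE), PSAT1 of serine synthesis by 0.74 ± 0.22, the cystine transporter SLC7A11 by 0.30 ± 0.09 and the stress-induced phosphatase subunit PPP1R15A by 1.06 ± 0.33, which became 0.67 without aligned 3. The list was divided after its values were seen. Its 8 chaperone and degradation genes had a mean of -0.24 (95% confidence interval -0.98 to 0.50 over cultures and -0.69 to 0.21 over pairs), with -0.05, -0.26 and -0.42 between the arrays numbered 1, 2 and 3. The other 17 had a mean of 0.72 (-0.15 to 1.59 over cultures and -0.92 to 2.36 over pairs). Without aligned 3 the list's median was 0.31. The list mean differed by 0.02 between the arrays numbered 1, by 0.41 between those numbered 2 and by 0.81 between those numbered 3. Targets of the mechanosensitive regulators YAP and TAZ rose with a median of 0.11 (camera adjusted p = 0.0402; adjusted p = 0.752 with an estimated correlation). F3, GADD45A and NT5E, at 0.67 ± 0.16, 0.67 ± 0.16 and 1.07 ± 0.29, were the 3 of 20 measured members that passed when adjusted over the list alone, against 0 over all genes, while TGFB2 differed by -0.30 ± 0.09. The YAP and TAZ call was lost without aligned 1 (adjusted p = 0.107), without random 3 (adjusted p = 0.757) and with the replicate number as a block (adjusted p = 0.0634), where 0 members passed over the list alone. The count of 3 without the block was 5 without aligned 1 and 0 without aligned 2 or any of the random arrays. The median was 0.16 without aligned 2, 0.19 without random 1 and 0.04 without random 3. The call was also lost with repeated quantile normalization (adjusted p = 0.0585) and array weights (adjusted p = 0.290), within a range of 0.00168 to 0.757 over 14 settings.

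Genes of cell cycle and mitosis fell on aligned fibers in the preset test (camera adjusted p = 1.39e-08; adjusted p = 0.752 with an estimated correlation). Of 38 measured genes 36 had a negative difference, and 0 passed over the list alone or over all genes in limma, with 5 at an unadjusted p under 0.05. The mitotic kinesin KIF20A differed by -0.68 ± 0.25 (SE), DLGAP5 by -0.56 ± 0.22, the topoisomerase TOP2A by -0.42 ± 0.17 and the cyclin CCNE2 by -0.36 ± 0.13. Without aligned 3 the median of the list was -0.14, and KIF20A, DLGAP5 and TOP2A were at -0.45, -0.34 and -0.26. The median was -0.11 without random 3. Most of this difference lay between the arrays numbered 3, with a list mean of -0.73, against 0.05 and -0.12 for those numbered 1 and 2. Replication-dependent histone genes fell with a median of -0.42 (camera adjusted p = 0.00156; adjusted p = 0.587 with an estimated correlation). Of 5 measured histone genes, H2BC12 at -0.44 ± 0.11 and H2BC5 at -0.33 ± 0.10 passed when adjusted over the list alone, 3 did so with the replicate number as a block, and 0 passed over all genes. The count over the list alone was 4 without aligned 1, 0 without aligned 2 and 0 without random 3, where the median was -0.26.

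Genes of neural stem and progenitor cells fell (camera adjusted p = 0.000383; adjusted p = 0.587 with an estimated correlation). Of 13 measured genes 11 had a negative difference, and ID3 passed when adjusted over the list alone, against 0 over all genes. Over the list alone 9 genes passed without aligned 1, 3 without aligned 2 and 4 without aligned 3. The transcription factors SOX4, SOX9 and SALL2 differed by -0.55 ± 0.18, -0.53 ± 0.18 and -0.44 ± 0.14 (SE). Without aligned 3 they were at -0.32, -0.31 and -0.28, and the median of the list was -0.28. The list mean differed by -0.16, -0.29 and -0.70 between the arrays numbered 1, 2 and 3. Astrocyte genes had a median of -0.15 and an adjusted p of 0.107 in camera, which became 0.0393 with the replicate number as a block, 0.00793 without random 3, 0.0146 with no filter and 0.0254 with array weights, within a range of 0.00793 to 0.322 over 13 settings. Of 10 measured astrocyte genes, ALDOC, an aldolase of the brain, at -0.29 ± 0.07 passed over the list alone, 3 passed so with the block, 2 without random 3, 0 with any other array left out and 0 over all genes.

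Hypoxia targets fell (camera adjusted p = 0.000263; adjusted p = 0.341 with an estimated correlation), and this was the 1 list of 37 that also passed fry, with an adjusted p of 0.0320. Of 24 measured genes 18 had a negative difference, and 0 passed over the list alone or over all genes in limma, while over the list alone 1 passed with the replicate number as a block, 9 without aligned 1, 2 without aligned 3 and 15 with array weights. BNIP3L and BNIP3, receptors for the removal of mitochondria, differed by -0.65 ± 0.20 and -0.34 ± 0.11 (SE), the glycolytic regulator PFKFB3 by -0.57 ± 0.19 and the collagen-modifying enzyme PLOD2 by -0.30 ± 0.10. Without aligned 3 the median of the list was -0.15, BNIP3L was at -0.40 and PFKFB3 at -0.33. STC2, a secreted glycoprotein on the same list named after its values were seen, differed by 1.01 in the other direction and by 0.47 without aligned 3. The list mean differed by -0.17, -0.09 and -0.18 between the arrays numbered 1, 2 and 3. Glycolysis genes fell with a median of -0.12 (camera adjusted p = 0.00790; adjusted p = 0.587 with an estimated correlation). Of 15 glycolysis genes 13 had a negative difference, with ENO2 at -0.25 ± 0.10 (-0.16 without random 3), PGK1 at -0.17 ± 0.08 and PGAM1 at -0.16 ± 0.07, and 0 passed over the list alone or over all genes.

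Genes of cholesterol biosynthesis fell in the preset test with a median of -0.33 (camera adjusted p = 0.0279; adjusted p = 0.799 with an estimated correlation). Of 18 measured genes 17 had a negative difference, and 0 passed over the list alone, over all genes or at an unadjusted p under 0.05 in limma. The sterol transfer protein STARD4 differed by -0.75 ± 0.59 (SE), TM7SF2, a sterol reductase, by -0.92 ± 0.45 and IDI1, an isomerase of the pathway, by -0.55 ± 0.50. The list mean differed by -0.08, -0.43 and -0.66 between the arrays numbered 1, 2 and 3, and with the replicate number as a block the adjusted p was 2.24e-07. Without the block, the median turned to 0.026 without aligned 3 (camera adjusted p = 0.945), where these genes were at -0.02, -0.41 and 0.01. That setting keeps random 3, whose list mean lay at -0.32 from the mean of all arrays, without the aligned array of its number. The median was -0.64 without aligned 1, -0.12 without random 1 and -0.59 without random 3, and the call was also lost without random 1 (adjusted p = 0.408) and without random 2 (adjusted p = 0.147), and was at adjusted p = 0.0522 with the stricter filter, within a range of 2.24e-07 to 0.945 over 14 settings. Fatty acid synthesis genes, which share their regulators with this pathway, had a median of -0.21 over 10 genes and an adjusted p of 0.186, which became 0.00850 with the replicate number as a block, 0.00330 without aligned 1, 0.00632 without random 3 and 0.0104 with array weights, within a range of 0.00330 to 0.905. In these settings the median of the fatty acid list was -0.21, -0.44, -0.40 and -0.24, in the order given. Over the list alone 0 of them passed, against 2 without aligned 1 and 2 with array weights. SREBF1, the regulator of that pathway, differed by -0.56 ± 0.21, and by -0.30 without aligned 3. Its 2 kept probe sets differed by -0.56 and -0.07. Targets of NRF2 and oxidative stress had a median of 0.10 over 16 genes and an adjusted p of 0.109, which became 0.0178 with the block and 0.0107 without random 3, within a range of 0.0107 to 0.698. The median of the NRF2 list was 0.10 with the block and 0.19 without random 3. TXNRD1, which reduces thioredoxin, differed by 0.40 ± 0.11, and over that list alone 0 genes passed without the block, 1 with it, 1 without aligned 1, 1 without random 1 and 4 with array weights.

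**Figure D3:**
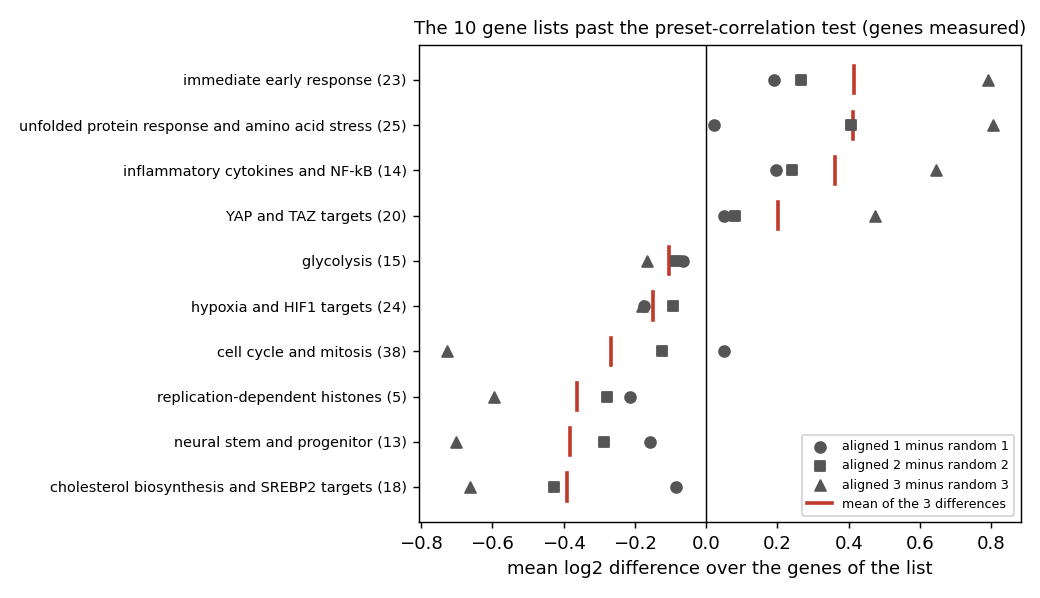
Mean log2 difference, aligned minus random, over the measured genes of the 10 lists that passed camera with a preset correlation, with the number of genes in parentheses. Circle, square and triangle stand for the differences between arrays numbered 1, 2 and 3, and the red bar for their mean. Hypoxia targets lie at -0.17, -0.09 and -0.18, while cell cycle genes lie at 0.05, -0.12 and -0.73, and none of the 10 lists passed with an estimated correlation.

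Lists tied to adhesion, motility and matrix did not pass camera. The adjusted p was 0.179 for integrins and focal adhesion, 0.985 for the actin cytoskeleton and its regulators, 0.107 for microtubules and motors, 0.213 for SRF and MRTF targets, 0.647 for the extracellular matrix and 0.626 for matrix proteases and their inhibitors. Without random 1 integrins and focal adhesion passed (adjusted p = 0.0344, range 0.0344 to 0.689), and without random 3 the extracellular matrix passed (adjusted p = 0.0107, range 0.0107 to 0.978), as it did with array weights (adjusted p = 0.0408). Microtubules and motors passed with no filter (adjusted p = 0.0188) and with array weights (adjusted p = 0.0422), within a range of 0.0188 to 0.251. Members of these 6 lists had differences of both signs, and 0 passed over the list alone. Without aligned 1, however, 5 integrin genes, 4 actin genes, 2 SRF and MRTF targets, 3 matrix genes and 3 protease genes passed so. Counts were 1 for SRF and MRTF targets without aligned 3, and 1 each for actin and proteases without random 1. With array weights 3 to 9 genes passed in each of the 6 lists. The integrin ITGAV differed by -0.35 ± 0.12, or -0.22 without aligned 3, and ITGA3 by 0.29 ± 0.10 (SE), the matrix enzyme LOX by -0.40 ± 0.11 and the protease receptor PLAUR by 0.51 ± 0.16. STAT3 targets had an adjusted p of 0.514, genes of the epithelial to mesenchymal transition 0.985, mesenchymal glioblastoma genes 0.372 and guidance genes of the semaphorin, ephrin, slit and netrin families 0.777. In these 4 lists 0 genes passed over the list alone. With an array left out, 3 mesenchymal and 2 guidance genes passed without aligned 1 and 2 guidance genes without random 1, and with array weights 8, 3, 3 and 8 genes passed in the order given.

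Among signalling lists, growth factor receptors and ligands had an adjusted p of 0.287 in camera, with 4 of 20 genes past the threshold when adjusted over the list alone, 1 with the replicate number as a block and 0 over all genes. Without random 1 the list passed (adjusted p = 0.0430, range 0.0430 to 0.871). The count of 4 was 0 without aligned 2, without random 2 and without random 3. PDGFA, HBEGF and FGF5 differed by 1.16 ± 0.32, 0.95 ± 0.25 and 0.42 ± 0.08 (SE), and IGFBP5 by -0.39 ± 0.10. The 4 kept probe sets of IGFBP5 ranged from -0.39 to -0.002 and the 3 of HBEGF from 0.10 to 0.95. Those of PDGFA ranged from 0.69 to 1.16 and those of FGF5 from 0.37 to 0.49. The TGF-beta and BMP list had an adjusted p of 0.973, with 3 of 18 genes past the threshold over the list alone, 1 without aligned 2, without random 1 or without random 3, and 0 over all genes. These were ID2 at -1.12 ± 0.20, the activin subunit INHBA at 0.43 ± 0.10 and BAMBI, a decoy receptor, at -0.48 ± 0.13. Notch had an adjusted p of 0.777, Wnt 0.843 and interferon 0.206, with 0 genes past the threshold over each list alone. Without aligned 1 there were 4 Wnt genes and 1 interferon gene, and with array weights 6 and 7. In the list of cyclin-dependent kinase inhibitors and p53 targets (adjusted p = 0.843) TP53INP1 passed over the list alone, at -0.61 ± 0.14, while 0 did with the block and 0 over all genes. That count was 4 without aligned 1, 3 without random 1 and 0 without aligned 2, random 2 or random 3. The remaining lists of the cell's basic functions gave adjusted p values of 0.0633 for DNA replication, 0.109 for heat shock, 0.242 for ribosomal proteins, 0.480 for oxidative phosphorylation, 0.372 for apoptosis regulators and 0.678 for reference genes. In these 6 lists 0 genes passed over the list alone. Without aligned 1, 2 apoptosis regulators did, and with array weights 7 DNA replication genes, 2 apoptosis regulators and 3 reference genes. DNA replication genes, with a median of -0.05, passed without aligned 3 (adjusted p = 0.0262) and without random 1 (adjusted p = 0.00635). They also passed with no filter (adjusted p = 0.0112), repeated quantile normalization (adjusted p = 0.0419), the mean of probe sets (adjusted p = 0.0451) and array weights (adjusted p = 0.00341), within a range of 0.00341 to 0.247. Heat shock genes passed with no filter (adjusted p = 0.0391, range 0.0391 to 0.724).

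Markers of other cell types did not pass camera as lists. The neuron list had an adjusted p of 0.985 over 8 genes, and SYT1 alone passed over the list, at 0.56 ± 0.14 (SE), against 0 genes with the replicate number as a block and 0 over all genes. That count was 2 without aligned 1 or aligned 3 and 0 without aligned 2, random 2 or random 3. Its member NEFL, a neurofilament subunit, differed by -1.38 ± 0.46, and by -0.79 without aligned 3. The oligodendrocyte list had an adjusted p of 0.678 over 5 genes, and CNP passed over the list alone, at -0.50 ± 0.13, against 2 genes with the block, 2 without random 1, 0 without aligned 2, random 2 or random 3, and 0 over all genes. The 2 kept probe sets of CNP differed by -0.50 and -0.04. Too few markers were measured for a list test of microglia (1 gene), endothelial cells (3 genes) and fibroblasts (3 genes).

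None of the 9 genes fixed in advance for migration, matrix, adhesion and glial identity passed over all genes in limma. STAT3 had the smallest p, with a log2 difference of -0.40 and a 95% confidence interval of -0.77 to -0.04 (unadjusted p = 0.0354, adjusted p = 0.472). It differed by -0.07, -0.27 and -0.86 between the arrays numbered 1, 2 and 3, and by -0.22 without aligned 3. The astrocyte filament GFAP read 5.22 ± 0.50 on aligned and 6.03 ± 0.72 on random fibers (SD, n = 3 each), a difference of -0.81 ± 0.38 (SE). The gelatinase MMP2 differed by -0.22, the intermediate filament NES by -0.24, fibronectin (FN1) by -0.12, the myosin light chain MYL9 by -0.04, the integrin ITGB1 by 0.01, the focal adhesion kinase PTK2 by 0.07 and beta-actin (ACTB) by 0.03. With an array left out, GFAP ranged from -1.20 to -0.50, MMP2 from -0.37 to -0.07, NES from -0.43 to -0.09, FN1 from -0.21 to -0.06 and PTK2 from 0.02 to 0.14, while MYL9 (-0.11 to 0.02) and ITGB1 (-0.02 to 0.05) changed sign. MYL9 and GFAP were each read by 1 probe set, with means of 5.82 and 5.63, near the median of all probe sets. Across the 9 genes and the members named from the lists, probe sets of the same gene disagreed in sign for BCL2L11, EBP, ELOVL5, ITGB4, PDLIM7 and TFRC.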

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

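The tests of RNA degradation and of noise in 1 array were chosen only after the result was seen.

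The bioB hybridisation spike, which lies outside the comparison of genes, read 9.28 on aligned 2, above the 3 random arrays, of which the highest read 9.16. All 3 aligned arrays averaged 9.20 ± 0.08 and the random arrays 9.12 ± 0.05 (SD, n = 3, exact permutation p = 0.3).

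Aligned 3 lay apart from the other 5 arrays. RNA degradation would raise the 3' minus 5' signal of both control genes, but that of beta-actin lay 0.650 SD above the mean of the other arrays and that of GAPDH 1.59 SD. Noise in 1 array with no relation to the substrate would leave its difference from random 3 unrelated to the other aligned minus random differences. Across genes, which are not independent replicates, that difference correlated with those of the arrays numbered 1 and 2 by 0.364 and 0.711, although they share no array. A state of the culture that differs also among aligned cultures would relate aligned 2 minus aligned 1 to aligned 3 minus random 3. These correlated by 0.321. Random 2 minus random 1, which holds no aligned array, correlated with aligned 3 minus random 3 by -0.128. A technical difference shared by several arrays could give such correlations too, so 0.364 and 0.711 bear only on noise confined to 1 array. A variable extent of the response, culture density or another unrecorded condition stay open along with topography itself.

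With weights per array, 2101 genes passed the adjusted threshold. The weighting is a likely source of this count: of the other 9 splits of the 6 arrays into 3 and 3, 4 called over 100 genes with weights, and the highest called 5320. The 3 splits with more genes than the real one gave single arrays weights of 27.3 to 36.4, and in these 3 and the real split the estimate of the weights stopped before it converged. Without weights each of the 10 splits called 0 genes.

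For the other splits, 10 in all, a share under 0.05 cannot be reached. Without weights, the count of genes past the adjusted threshold was 0 in the real split and 0 at most in the others, so all 10 splits gave as many, and the same held for probe sets (10 splits, 0 and 0). At an unadjusted p under 0.05 the real split gave 1303 genes and the highest other 1440, in the split with aligned 1, random 1 and random 2 together, so 2 of the 10 gave as many. For gene lists in camera the real split gave 10 and the highest other 14, and 5 of the 10 gave as many. Taking the replicate numbers as pairs, the 3 other splits that part all 3 pairs gave 46, 85 and 303 genes at an unadjusted p under 0.05 and 5, 5 and 13 lists, against 1303 and 10. Each of these 3 differs from the real split by an exchange of the substrates within 1 pair, while the split that gave 1440 genes leaves pair 1 together. These splits are too few to reach a share under 0.05. The pairing that selects them was itself taken from the same values, so no conclusion on the substrate is drawn from them.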

How the results depend on the processing

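The alternatives for counts at an unadjusted p under 0.05 and for list members past the threshold over their list alone were added after the data were seen. In limma 0 genes passed the adjusted threshold under each filter, scaling, prior, test and probe set choice, with the replicate block (0) and with any array left out, except with array weights, whose estimate over genes did not converge and which gave 2101 genes (1062 higher and 1039 lower) and 291 probe sets. The looser threshold of an unadjusted p under 0.05 with a 1.5-fold change gave 220 genes and 463 probe sets. Probe sets ranged from 0 to 1 with an array left out, the 1 coming without aligned 1. Genes at an unadjusted p under 0.05, 1303 as reported, were 851 with the stricter filter, which tests fewer genes (7804). They were 835 in the ordinary test, 4326 with array weights and 624 to 2491 with an array left out. With the replicate block they were 1687, or 13.6%, and the lowest adjusted p in limma was 0.362. List members past the threshold over their list alone, 26 as reported, were 41 with no filter, 17 with the stricter filter, 215 with array weights, 1 in the ordinary test and 5 to 105 with an array left out.

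Of 10 lists called by camera, 0 were called with an estimated correlation and 1 with fry, and 9 to 13 with an array left out. The replicate block gave 12, with 9 of the 10 among them. It lost YAP and TAZ targets, added the astrocyte, fatty acid and NRF2 lists, and changed no other list call. The median of cholesterol genes reversed to 0.026 without aligned 3, a setting that keeps random 3 without the aligned array of its number. It ranged from -0.64 to 0.026 with an array left out. Single lists were followed in 14 settings with a preset correlation. Wherever tested in these, the lists of cell cycle, immediate early, hypoxia, neural stem, stress, inflammatory, histone and glycolysis genes kept their call. The omission of probe sets that share sequence was not among these settings. It gave 7 lists past the camera threshold and 15 list members past the threshold over their list alone. Which lists these 7 were was not recorded, so calls of single lists in that setting are unknown. The stricter filter ended the cholesterol call (adjusted p = 0.0522, range 2.24e-07 to 0.945) and left fewer than 5 genes in the histone, astrocyte, neuron and oligodendrocyte lists, which then had no test. The first principal component held 53.7% of the variance with no filter. Among named genes, 120 calls were gained, all with array weights, and 49 values of genes or lists that were not called changed sign. The cause of these changes was not tested, beyond fewer genes or arrays where a setting removes them.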

Other observations

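The 3 tests on stress genes in this part were chosen only after the result was seen, and so were the genes named in it outside the rule for named genes.

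The largest differences on aligned fibers included genes outside the lists or not described so far, none past the adjusted threshold in limma. The cannabinoid receptor gene CNR1 read 5.94 ± 1.84 on aligned and 7.99 ± 0.34 on random fibers (SD, n = 3 each), and the receptor tyrosine kinase PDGFRA read 8.05 ± 1.85 against 10.00 ± 0.13. PDGFRA differed by -0.44, -1.35 and -4.04 between the arrays numbered 1, 2 and 3, while its ligand PDGFA differed by 0.19, 1.17 and 2.13. The protease inhibitor-like gene PI15 differed by -1.82 ± 0.39 (SE), the neuropeptide Y receptor NPY1R by -1.52 ± 0.74, the chemokine CXCL14 by -1.63 ± 0.80 and SOX2-OT, a transcript that overlaps the stem cell gene SOX2, by -1.35 ± 0.42. Aligned means of PI15 and NPY1R were 5.01 and 5.46, below the array medians of 5.63 to 5.66, so these sizes rest on dim aligned values. Without aligned 3 the differences of CNR1, PDGFRA, PI15, NPY1R, CXCL14 and SOX2-OT were -1.04, -0.90, -1.35, -0.53, -0.68 and -0.79.

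Other genes were picked singly for large positive differences, and no class of genes was tested through them. GDF15, a secreted stress cytokine, differed by 1.69 ± 0.59 (SE), CBS of cysteine synthesis by 1.23 ± 0.39, the arginine-making enzyme ASS1 by 1.25 ± 0.50, the mitochondrial enzyme PCK2 by 1.20 ± 0.42, the stress protein NUPR1 by 1.20 ± 0.45 and the transcription factor JDP2 by 1.26 ± 0.47. Between the arrays numbered 1 the differences of CBS, ASS1, PCK2, NUPR1 and JDP2 lay between -0.03 and 0.05, while between those numbered 2 they lay between 1.15 and 1.47. Without aligned 3 the differences of GDF15, CBS, ASS1, PCK2, NUPR1 and JDP2 were 1.04, 0.83, 0.69, 0.72, 0.66 and 0.69.

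The stress list rested in part on aligned 3. Without that array its mean difference was 0.28, with a 95% confidence interval over cultures of -0.19 to 0.74. The pairs numbered 1 and 2 differed by 0.02 and 0.41, and random 1 lay beside aligned 1, at 0.02 and 0.04 from the mean of all arrays. A signal of aligned 3 alone and a difference between the substrates therefore cannot be told apart with so few cultures. General stress of the endoplasmic reticulum would raise its chaperones and degradation genes. The mean of 8 of these was -0.24, but its intervals, -0.98 to 0.50 over cultures and -0.69 to 0.21 over pairs, hold both signs, so this explanation stays open too. Aligned cultures may also have used up more of the medium: the labels hold 0 recorded values on cell number or medium at harvest, so that explanation and a response to topography cannot be told apart.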
